A study of Mus musculus with 10 samples.

How the data were processed

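Gene expression was measured on 10 single-colour Illumina mouse BeadChip arrays. The arrays fell into 5 groups of 2: neural stem cells from female mice (fNSC), parthenogenetic neural stem cells (pNSC), induced pluripotent cells made from parthenogenetic neural stem cells with Oct4 and Klf4 (piPS-2F), parthenogenetic embryonic stem cells sorted for the surface antigen SSEA-1 (pESC-B), and female embryonic stem cells labelled OG2 (fESC). Groups and replicate numbers were taken from the sample labels. The labels disagree in 2 places. The title of the female embryonic line carries an extra B that its description lacks, and 1 label of piPS-2F replicate 2 names Klf5 where the others name Klf4. Per the labels, total RNA was purified on columns with DNA digestion, amplified linearly and labelled with biotin. The series description speaks of 5 samples analysed in duplicate. The pairs may therefore be technical duplicates, and every p-value measures only the spread between duplicate arrays.

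The authors deposited a table that was not normalized, with an intensity per probe and array on a linear scale. Its values show that background had already been subtracted, as between 22.9% and 28.3% of the intensities of an array lay below 0. The same deposited table holds a detection p-value for every probe on every array. BeadStudio 3.2 is named in the submitters' processing notes. A second deposited table holds the authors' processed values, taken here as log2 expression from their range of 1.30 to 15.26, since no source names the base. Its 10 columns share 1 distribution to within 0.000525 at every rank, with a median of 3.92 in each column. Each column ranked the probes exactly as the intensities of its own array did (Spearman correlation 1.0). RMA and lumi are named in the submitters' processing notes without their order or settings. The processed values served as an alternative only. The genome build behind the probe annotation is not given in the sources used here, so no coordinates are printed.

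Of 25697 probes, 23978 were paired with 1 gene symbol and 1719 with none. A RefSeq gene table of the assembly GRCm38.p6 held the Entrez identifier of 23962 probes, changed no symbol, and was used for names and for the order of genes along chromosomes only.

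The intensities were processed with limma 3.58.1 in R 4.3.3. Its function neqc fitted the background from the detection p-values, added an offset of 16, normalized the arrays by quantiles and took log2. The result is called the log2 signal. Probes were kept when their detection p-value was under 0.01 on both arrays of at least 1 group. This left 13564 probes, 12776 of them with a symbol. For genes with several kept probes the one with the highest mean signal was used, which gave 9220 genes, of which 2503 had 2 or more kept probes. Quantile normalization assumes that the arrays share 1 distribution of signals, and the offset shrinks the differences of dim genes.

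A linear model with 1 mean per group was fitted to all 10 arrays, followed by empirical Bayes moderation (lmFit and eBayes, 5 residual degrees of freedom). All groups shared the estimate of the spread because a pair of groups alone leaves too few degrees of freedom. Differences are on the log2 scale with their standard error (SE). Group levels are the mean and standard deviation (SD) of 2 arrays. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. A gene was called higher or lower, or said to have risen or fallen, at an adjusted p under 0.05 and a difference of at least 2-fold. In all, 6 pairwise comparisons and 2 interaction contrasts were made. An interaction contrast asks whether the difference between a parthenogenetic and a female line is the same in pluripotent and in neural stem cells. Where a gene was detected on neither array of 1 group, its fold is given as a lower bound. The bound sets the mean of the brighter group against, per array of the dimmer group, the higher of the probe's own signal and the lowest signal of a detected probe.

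Before the data were examined, 17 gene lists with 318 genes were fixed. They cover pluripotency, neural stem cells, paternally and maternally expressed imprinted genes, germline genes repressed by DNA methylation in somatic cells, epithelial and mesenchymal genes, feeder fibroblasts, neurons, oligodendrocytes, microglia, extraembryonic endoderm, trophectoderm, primed epiblast and mesoderm, MHC class I presentation, X inactivation with Y-linked genes, and the cell cycle. Of the listed genes 277 had a probe. Each list with at least 3 tested genes was compared with all other genes by camera, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. An estimated correlation and the rotation test fry were the alternatives.

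The rule for naming genes was fixed at the same time. It takes the 6 highest and 6 lowest called genes per pairwise comparison whose arrays do not overlap, without clone-type symbols. It adds up to 4 called members of each list described, or up to 2 members where none was called. Pou5f1 (Oct4), Klf4, Sox2, Myc and Nanog are named in comparisons with piPS-2F, Xist in comparisons of parthenogenetic with female lines, and Y-linked genes as a check of the labels. Up to 12 called imprinted genes are named per comparison. For interaction contrasts the 4 highest and 4 lowest called genes and the imprinted genes are named, and 6 genes per direction for those that set piPS-2F apart from both embryonic lines.

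The model fit and the calling of genes were tested on simulated log2 signals. These were drawn around each gene's mean over all arrays with the moderated spread of these arrays, with 50 of 9220 genes changed at each of several folds. Background correction, offset, normalization, probe filter and choice of probe were not part of this test. In the pairwise comparisons, 98% to 100% of 3-fold changes, 30% to 64% of 2-fold changes and 0% to 2% of 1.5-fold changes were called, with 0 to 3 unchanged genes called per comparison. In the interaction contrasts, 96% of 3-fold changes were called, with 4 and 7 unchanged genes called.

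The alternatives were another background correction, none, the authors' processed values, no filter or a stricter filter on dim probes, the mean of a gene's probes, fits restricted to the arrays of a comparison, an intensity trend with robust moderation, the adjusted p alone, a test against a minimum fold, the replicate number as a block, and the omission of each array in turn. Scaling by the median without quantile normalization and a crossed pairing were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and estimated correlations with statmod 1.5.0. The number of arrays limits the precision of every value.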

Results

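Transcript levels were measured in 5 mouse cell populations with 2 arrays each. Parthenogenetic cells come from embryos that developed without a sperm and so carry maternal chromosomes only. The series asked how induced pluripotent cells made from parthenogenetic neural stem cells compare with their cells of origin and with embryonic stem cells. Between 9938 and 11837 of 25697 probes were detected per array (38.7% to 46.1%). The mean signal was 287 to 327 on the arrays of piPS-2F and pESC-B and 476 to 625 on those of the other 3 groups. Comparisons of piPS-2F or pESC-B with any of these 3 groups therefore also compare dimmer with brighter arrays. No label names a batch, so this difference and the groups cannot be told apart.

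Duplicate arrays correlated at 0.990 to 0.996 across genes, which are not independent replicates. The piPS-2F arrays lay nearest to those of pESC-B (mean r = 0.955), followed by fESC (0.905), and far from those of their cells of origin, pNSC (0.675). As piPS-2F and pESC-B are also the dimmer groups, line and array brightness cannot be told apart in the order of pESC-B and fESC. The 2 neural lines correlated at 0.947 and the 2 embryonic lines at 0.896. The first principal component, which held 75.2% of the variance, separated neural from pluripotent lines, and the second held 13.3%.

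**Figure D1:**
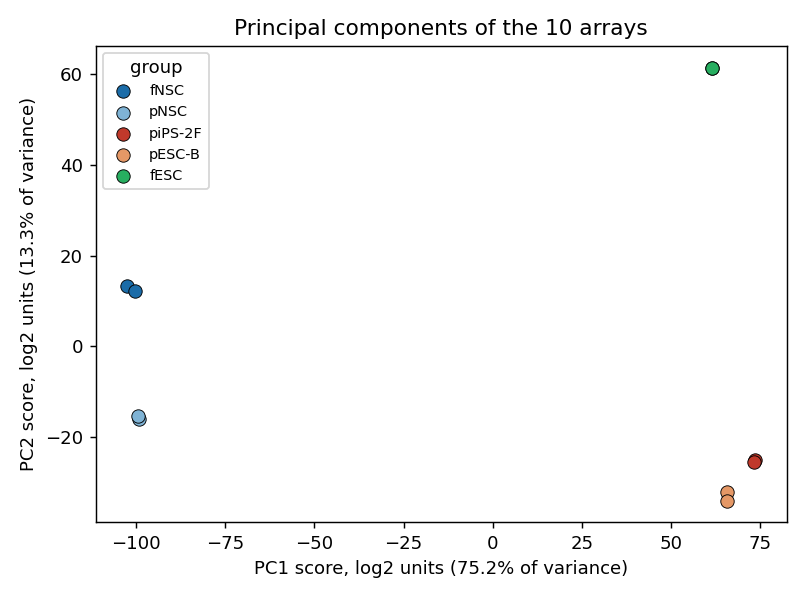
Scores of the 10 arrays on the first (x axis, 75.2% of the variance) and second (y axis, 13.3%) principal components of the log2 signals of 9220 genes, with 1 point per array and 1 colour per group. Both arrays of each group lie close together, and the neural lines lie apart from the 3 pluripotent lines along the x axis.

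As a check of the labels, probes for the Y-linked genes Kdm5d and Eif2s3y were detected on no array, and Uty was detected on 1 of 2 arrays in fNSC, piPS-2F and fESC. Xist, the RNA that coats the inactive X chromosome, had log2 signals of 9.78 ± 0.44 in fNSC and 9.94 ± 0.55 in pNSC (SD, n = 2). It reached 7.02 ± 0.32 in piPS-2F and 6.09 in pESC-B, where a second probe was not detected (5.10), and was not detected in fESC.

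The comparison of piPS-2F with pNSC asks what changed during reprogramming. The genes that rose most were undetected in pNSC by the probes used. Dppa5a was at least 668-fold higher in piPS-2F, Dnmt3l at least 308-fold, Ooep, a maternal factor of oocytes, at least 239-fold, and Dppa4 at least 186-fold, although another Dppa4 probe gave 0.12. Pou5f1 rose at least 187-fold (13.07 ± 0.12 against 4.50 ± 0.08, SD, n = 2) and Nanog at least 84.2-fold. The genes that fell most included the endothelin receptor gene Ednrb, at least 582-fold, Tril, at least 305-fold, and Bcan, which encodes a brain proteoglycan, at least 186-fold. Olig1, a transcription factor of the oligodendrocyte lineage, differed by -9.20 ± 0.14 (SE) and remained detected on 1 of 2 piPS-2F arrays. The largest adjusted p among these genes was 3.2e-10.

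Of 34 tested pluripotency genes, 32 were higher in piPS-2F and none was lower (camera adjusted p = 1.1e-13). Of 30 neural stem cell genes, 27 were lower and none was higher (adjusted p = 9.4e-12), among them Gpm6a, at least 108-fold, and Mt3, with a difference of -7.20 ± 0.25. Both calls held with an estimated correlation (adjusted p = 0.0043 and 0.048). Of the 4 classical reprogramming factors, Klf4 rose 7.97-fold (adjusted p = 6.3e-07), Sox2 differed by 0.54 ± 0.19 (adjusted p = 0.025, under the 2-fold minimum) and Myc by -0.34 ± 0.18 (adjusted p = 0.12). The second Sox2 probe gave -3.13. Whether the probes separate the endogenous Oct4 and Klf4 transcripts from introduced ones was not tested.

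Epithelial genes were higher in piPS-2F than in pNSC, with 7 of 10 called (adjusted p = 0.0015, and 0.073 with an estimated correlation). They included Cdh1, the gene of E-cadherin, at least 18.4-fold, and the claudin gene Cldn4, at least 18.9-fold. Of 11 mesenchymal genes, 6 fell and 1 rose (adjusted p = 0.058). The transcription factor gene Zeb1 fell by 4.32 ± 0.16 and Ncam1 fell at least 37.7-fold. Ncam1, Cdh2 and Vim are also in the neural stem cell list, so the mesenchymal count partly repeats the fall of neural stem cell genes. Trophectoderm genes were higher, with 7 of 8 called (adjusted p = 0.0042, and 0.16 with an estimated correlation). Tfap2c, which is also active in pluripotent and germ cells, was at least 98.9-fold higher. Of 8 germline genes, 5 rose (adjusted p = 0.17), led by Tex19.1, at least 89.6-fold.

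Imprinted genes, which are expressed mainly from 1 parental copy, moved both ways between these lines. Of 15 paternally expressed genes, 9 were higher and 2 lower in piPS-2F (adjusted p = 0.023, and 0.15 with an estimated correlation). Snrpn, undetected in pNSC, was at least 23-fold higher, Igf2, a fetal growth factor gene, at least 30-fold, and Mkrn3 at least 6.61-fold. The second Snrpn probe differed by 1.05. Ndn rose by 3.23 ± 0.14. Of 16 maternally expressed genes, 8 were higher and 6 lower (adjusted p = 0.86). Phlda2 was at least 75.6-fold and Grb10, an adaptor that restrains growth signals, at least 36.1-fold higher, while Gnas fell by 4.34 ± 0.16.

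The other lists gave mixed counts in piPS-2F against pNSC, and none of them was called. Feeder fibroblast genes were higher for 7 of 12 members and lower for 1 (adjusted p = 0.063), including Acta2 at 3.23 ± 0.15. That list was called without pNSC replicate 1 or piPS-2F replicate 1 (adjusted p = 0.024 to 0.049), and the mesenchymal list without either array of pNSC or piPS-2F replicate 1 (0.0486 to 0.0494). Of 8 neuronal genes, 2 rose, among them Stmn2, at least 36.0-fold, and 6 fell, among them Map2 by 4.70 ± 0.15 (adjusted p = 0.19). Oligodendrocyte genes went 2 up and 2 down of 5 (adjusted p = 0.86), and extraembryonic endoderm genes 5 up and 3 down of 9 (adjusted p = 0.72). Primed epiblast genes were higher for 4 of 8 members (adjusted p = 0.17), including the DNA methyltransferase gene Dnmt3b at 7.40 ± 0.20. Of 7 genes of MHC class I presentation, 4 fell (adjusted p = 0.16), with B2m at -2.47 ± 0.21. Cell cycle genes went 8 up and 5 down of 15 (adjusted p = 0.50), with Mcm3 at 3.42 ± 0.13 and Ccnd2 at -5.28 ± 0.22. The 1 tested microglial gene, Aif1, undetected in pNSC, was at least 1.05-fold higher (adjusted p = 0.0075, under the 2-fold minimum), and Xist fell by 2.93 ± 0.29.

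In total 4926 of 9220 genes were called between piPS-2F and pNSC, 2491 higher and 2435 lower. The arrays of piPS-2F were dimmer than those of pNSC (mean signal 287 and 291 against 617 and 625).

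The female lines provide the same contrast of pluripotent with neural cells on other arrays. Between fESC and fNSC, 4485 genes were called, 2202 higher and 2283 lower in fESC. Ooep was at least 353-fold, Dnmt3l at least 255-fold, Pou5f1 at least 252-fold and Dppa4 at least 154-fold higher in fESC. Ednrb was at least 351-fold and the sulfotransferase gene Chst2 at least 118-fold lower, and the glutamate transporter gene Slc1a3 fell by 7.66 ± 0.15. Of the pluripotency genes, 33 of 34 were higher (adjusted p = 1.6e-15), and of the neural stem cell genes 28 of 30 were lower (adjusted p = 1.0e-11), including Fabp7, at least 70.1-fold. Epithelial genes were higher for 9 of 10 members (adjusted p = 4.9e-05). These 3 calls held with an estimated correlation (adjusted p = 0.0031, 0.033 and 0.033). Germline genes were higher for 6 of 8 members (adjusted p = 0.012, and 0.087 with an estimated correlation), trophectoderm genes for 8 of 8 (0.00045 and 0.087), and mesenchymal genes lower for 8 of 11 (0.013 and 0.087). The mesenchymal list shares Ncam1, Cdh2 and Vim with the neural stem cell list, so these 2 calls are not separate.

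Feeder fibroblast genes were higher in fESC than in fNSC for 8 of 12 members (adjusted p = 0.046, and 0.31 with an estimated correlation), with Acta2 at 4.87 ± 0.15. Extraembryonic endoderm genes were higher for 7 of 9 (adjusted p = 0.049, and 0.17 with an estimated correlation), including Lama1, at least 4.86-fold. Both calls sat at the threshold. The first was lost without fNSC replicate 1 (adjusted p = 0.052). The second was lost without either array of fNSC, either array of pESC-B or fESC replicate 2 (adjusted p = 0.052 to 0.079).

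The change from pNSC to piPS-2F largely ran along the difference between fESC and fNSC, although the 2 comparisons share no array. Genes higher in both numbered 1611, against 595 for independent lists, and genes lower in both 1638, against 603. Only 22 genes higher and 47 genes lower in piPS-2F than in pNSC moved the opposite way between the female lines. The differences correlated at 0.83 across genes, which are not independent replicates.

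The comparison of piPS-2F with pESC-B sets reprogrammed against embryonic cells of the same parental origin, on arrays of similar brightness. It called 871 genes, 415 higher and 456 lower in piPS-2F, and 391 with an offset of 50 (180 and 211). Chromosome 1 held 52 of the higher and 15 of the lower genes, and the X chromosome 41 and 10. These chromosomes held 452 and 328 of the 9220 tested genes. Their genes lay higher in median than those of the other autosomes, by 0.369 and 0.314. How many of the calls follow these shifts was not tested. The anion exchanger gene Slc4a3 was 41.2-fold higher (5.37 ± 0.13), and Zscan4c, a gene of embryos at the 2-cell stage and of rare embryonic stem cells, at least 18.4-fold. Cdc42ep2 was 18.4-fold higher, the lens crystallin gene Crygd at least 9.22-fold, and Wdr20rt and Pramel20 at least 9.49-fold and 7.19-fold. Olig1 was lowest, with a difference of -5.70 ± 0.14. Wdr46 fell at least 15.4-fold, Ctsc, the cathepsin C gene, at least 13.3-fold, Trim59 at least 12.4-fold, and Cops8 and Rpusd4 differed by -4.88 ± 0.22 and -4.73 ± 0.21. The largest adjusted p among these 12 genes was 3.6e-07.

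Core pluripotency genes differed little between piPS-2F and pESC-B. Of the 34 listed, 2 were higher and none was lower (adjusted p = 0.52): the Ras family gene Eras, by 2.03 ± 0.18, and Prdm14, whose call ended with an offset of 50, without background correction and with median scaling. Nanog differed by 0.08 ± 0.15 (adjusted p = 0.73), Sox2 by 0.31 ± 0.19 (0.26), Myc by 0.44 ± 0.18 (0.10), Pou5f1 by 0.63 ± 0.16 (0.013) and Klf4 by -0.70 ± 0.22 (0.039). The last 2 were under the 2-fold minimum. Epithelial genes were lower in piPS-2F for 6 of 10 members (adjusted p = 0.00028, and 0.085 with an estimated correlation), including Cldn6 at -1.50 ± 0.14 and Cldn4 at -1.41 ± 0.13. Germline genes were higher for 4 of 8 (adjusted p = 0.0012, and 0.085 with an estimated correlation), including Tex19.1, a gene active in germ cells and placenta, at 1.78 ± 0.22 and Taf7l at 1.75 ± 0.20.

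Among imprinted genes, 4 of 15 paternally expressed ones were higher in piPS-2F than in pESC-B (adjusted p = 0.092). Mest was at least 3.94-fold higher (7.50 ± 0.31 against 4.87 ± 0.06, undetected in pESC-B), Snrpn rose by 2.07 ± 0.14, Inpp5f by 1.57 ± 0.17 and Impact by 1.01 ± 0.15. The other Mest probes differed by as little as 0.78 and the second Snrpn probe by 1.22. Impact was no longer called without piPS-2F replicate 1 or pESC-B replicate 1. Of 16 maternally expressed genes, 3 were lower and none was higher (adjusted p = 0.17): Grb10 by -1.64 ± 0.22, Gnas by -1.31 ± 0.16 and H13 by -1.23 ± 0.16. The mean of its probes left H13 at -0.998, under the 2-fold minimum.

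Feeder fibroblast genes were higher in piPS-2F than in pESC-B for 3 of 12 members (adjusted p = 0.034, and 0.42 with an estimated correlation): Acta2 by 1.12 ± 0.15, Dcn by 1.18 ± 0.27 and Col1a1 by 1.02 ± 0.23. The list was no longer called without piPS-2F replicate 2 (adjusted p = 0.18), nor was Acta2 or Col1a1, which was also lost without pESC-B replicate 2, and Dcn was lost without pESC-B replicate 1 and in a fit to the 4 arrays of the comparison alone. Of the 5 groups only pESC-B is labelled as sorted. Cell cycle genes were called as a list (adjusted p = 0.045, and 0.22 with an estimated correlation) with 1 of 15 members higher, the replication gene Mcm3 at 1.07 ± 0.13. That call was lost without any single array of pNSC, piPS-2F, pESC-B or fESC (adjusted p = 0.052 to 0.10). Of 8 primed epiblast genes, Otx2 rose by 1.98 ± 0.24, while Fgf8 fell by 3.11 ± 0.20 and Mixl1 fell at least 1.93-fold (adjusted p for the list = 0.17, and 0.043 without pESC-B replicate 1).

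The comparison of piPS-2F with fESC called 2183 genes, 1060 higher and 1123 lower, relative to a median over all genes of 0.15. The balance depended on the processing: an offset of 50 gave 1269 genes, 469 higher and 800 lower, and the authors' values gave 2829, 1479 higher and 1350 lower. Slc4a3 was 38.2-fold higher in piPS-2F (5.25 ± 0.13), Cdc42ep2 at least 18.9-fold, Nod1, a sensor of bacterial peptides, at least 10.9-fold, and Abcc10 and A3galt2 at least 5.92-fold and 3.96-fold. The ribosomal protein gene Rpl22l1 was at least 34.8-fold and Tma7 at least 17.5-fold lower, and Nono and the stress response gene Atf4 each fell by 4.83, with SE of 0.21 and 0.13. Mpv17l and Terf2ip differed by -4.92 ± 0.19 and -4.87 ± 0.13, but other probes for them differed by as little as -0.0003 and -0.32. Among called genes with several kept probes, 52.6% had another probe that differed by under 0.5. The lowest share of the 6 pairwise comparisons was 13.2%, between fESC and fNSC. It was 29.9% in piPS-2F against pESC-B, 26.9% in pNSC against fNSC and 21.7% in piPS-2F against pNSC. The arrays of piPS-2F were also dimmer than those of fESC (mean signal 287 and 291 against 476 and 495).

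Of 34 pluripotency genes, 6 were lower and 2 higher in piPS-2F than in fESC (adjusted p = 0.25). Tdgf1, the gene of the Nodal co-receptor Cripto, fell by 3.73 ± 0.23 and Jarid2, detected in fESC only, fell at least 7.13-fold, with Klf4 at -2.21 ± 0.22, where another probe gave -0.62, and Tcl1 at -1.79 ± 0.18. In pESC-B, whose arrays were also dimmer, Tdgf1 and Tcl1 differed from fESC by -3.63 and -1.90, and Jarid2 was at least 6.83-fold lower. Pou5f1 differed by -0.28 ± 0.16 (adjusted p = 0.15), Sox2 by 0.33 ± 0.19 (0.17, with its second probe at -3.79) and Nanog by -0.97 ± 0.15 (0.00031, under the 2-fold minimum). Myc was called higher at 1.13 ± 0.18 but was undetected in fESC, and no lower bound of its fold could be given. Its call ended with an offset of 50 or median scaling. Epithelial genes were lower for 5 of 10 members (adjusted p = 0.024, and 0.23 with an estimated correlation), including the keratin genes Krt18 at -2.40 ± 0.14 and Krt8 at -1.55 ± 0.14 and Cdh1 at -1.52 ± 0.13.

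Paternally expressed imprinted genes were lower in piPS-2F than in fESC for 7 of 15 members and higher for none (adjusted p = 0.00035, and 0.11 with an estimated correlation). Mest fell by 3.27 ± 0.18, the amino acid transporter gene Slc38a4 differed by -3.23 ± 0.33 and Snrpn by -2.82 ± 0.14, and Peg10 and Peg3 fell at least 4.53-fold and 3.85-fold. Of 16 maternally expressed genes, 6 were higher and 1 lower (adjusted p = 0.28). Cdkn1c, a cell cycle inhibitor gene, rose by 2.40 ± 0.20, Phlda2 by 1.79 ± 0.14 and Grb10 by 1.66 ± 0.22. Ube3a fell by 2.01 ± 0.21, but its other probe gave 0.21. Xist was higher at 1.73 ± 0.29 (at least 2.15-fold, undetected in fESC), and under the 2-fold minimum with an offset of 50.

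The comparison of pNSC with fNSC sets a parthenogenetic against a female neural line. The arrays of pNSC were brighter (mean signal 617 and 625 against 479 and 527). Origin cannot be told apart here from other differences between the 2 lines, such as strain or culture. It called 1046 genes, 471 higher and 575 lower in pNSC, and 593 with an offset of 50 (258 and 335). Paternally expressed imprinted genes were lower for 9 of 15 members and higher for none (adjusted p = 5.1e-08, and 0.025 with an estimated correlation). Mest, one of the most reduced genes, was at least 156-fold lower (4.43 ± 0.06 against 12.81 ± 0.27), Snrpn at least 34.5-fold and Mkrn3 at least 4.52-fold. Ndn differed by -5.59 ± 0.14, Nnat by -4.13 ± 0.25, Nap1l5 by -2.69 ± 0.21 and Impact by -1.52 ± 0.15. Peg3 and Peg10 fell at least 1.66-fold and 1.33-fold, calls that ended with an offset of 50. The second Snrpn probe differed by -1.04. Of 16 maternally expressed genes, 2 were higher and none lower (adjusted p = 0.80), Cdkn1c at 3.08 ± 0.20 and H13 at 1.26 ± 0.16. Xist differed by 0.16 ± 0.29 (adjusted p = 0.72).

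Beyond imprinted genes, Chchd10, a gene of the mitochondrial intermembrane space, was 60.8-fold higher in pNSC (5.93 ± 0.14). Mfap2, which encodes a microfibril protein, was at least 23.1-fold, Paqr7 at least 18.2-fold and the transporter gene Slc6a15 at least 9.27-fold higher, and Cplx1, a regulator of synaptic release, rose by 4.53 ± 0.23. Mdk was at least 21.8-fold higher by the probe used, but another of its probes gave -0.10. The interferon-induced gene Ifitm3 fell by 6.79 ± 0.16, and the BMP antagonist gene Sostdc1 and the claudin gene Cldn12 fell at least 36.3-fold and 28.5-fold. Of 30 neural stem cell genes, 7 rose and 4 fell (adjusted p = 0.33), among them the Notch target Hes5 at 3.87 ± 0.15 and Mt3 at 2.43 ± 0.25. Of 11 mesenchymal genes, 5 fell (adjusted p = 0.43), including Sparc at -2.53 ± 0.15, and of 12 feeder fibroblast genes, 4 rose and 3 fell (adjusted p = 0.54). Neuronal and oligodendrocyte genes were higher for 2 of 8 and 2 of 5 members (adjusted p = 0.064 and 0.060). The first list was called without pNSC replicate 1 (0.035), and the second without pNSC replicate 2, either array of piPS-2F or either array of fESC (0.028 to 0.042).

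The comparison of pESC-B with fESC does the same in embryonic stem cells, with the same limit. It called 2487 genes, 1311 higher and 1176 lower, relative to a median over all genes of 0.15. An offset of 50 gave 1503 genes, with 686 higher and 817 lower. Zscan4c and Tcstv3, both active at the 2-cell stage, were at least 47.1-fold and 33.2-fold lower in pESC-B, Mest at least 38-fold and Pramel37 at least 21-fold. Nod1 was at least 12.4-fold, Celsr3, a cadherin gene of cell polarity, at least 11.7-fold and Ahcy at least 6.80-fold higher. The Wnt target Sp5 rose by 3.78 ± 0.22, and the immediate early genes Fosb and Fos rose by 3.84 ± 0.38 and 3.36 ± 0.20. Nono differed by -5.01 ± 0.21 and Mpv17l by -4.93 ± 0.19, with another Mpv17l probe at -0.46. The arrays of pESC-B were dimmer (mean signal 287 and 327 against 476 and 495), and 45.6% of the called genes with several kept probes had another probe that differed by under 0.5.

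Paternally expressed imprinted genes were lower in pESC-B than in fESC for 8 of 15 members and higher for 1 (adjusted p = 0.00040, and 0.11 with an estimated correlation). Snrpn differed by -4.89 ± 0.14, Slc38a4 by -3.70 ± 0.33, Impact by -2.07 ± 0.15 and Inpp5f by -2.05 ± 0.17, and Peg10 and Peg3 fell at least 4.34-fold and 3.69-fold. Of 16 maternally expressed genes, 9 were higher and 2 lower (adjusted p = 0.12). Grb10 rose by 3.30 ± 0.22, H13 by 2.24 ± 0.16, Cdkn1c by 2.21 ± 0.20 and Phlda2 by 1.86 ± 0.14, while Ube3a fell by 2.65 ± 0.21, with its other probe at -0.56. Germline genes were lower for 6 of 8 members (adjusted p = 0.0050, and 0.13 with an estimated correlation), including the tubulin genes Tuba3b and Tuba3a at -3.53 ± 0.16 and -3.12 ± 0.19, whose products are near-identical. Xist, undetected in fESC, was at least 1.13-fold higher (adjusted p = 0.037, under the 2-fold minimum), and its second probe, undetected in both lines, differed by -0.0047.

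Primed epiblast genes were higher in pESC-B than in fESC for 5 of 8 members and lower for none (adjusted p = 0.049, and 0.47 with an estimated correlation). The fibroblast growth factor genes Fgf8 and Fgf5 were at least 6.30-fold and 3.79-fold higher. The list was no longer called without either array of fNSC, either array of piPS-2F, pESC-B replicate 2 or fESC replicate 1 (adjusted p = 0.050 to 0.070). Of 34 pluripotency genes, 9 were lower and 2 higher (adjusted p = 0.12), with Tdgf1 at -3.63 ± 0.23 and Eras at -2.34 ± 0.18.

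**Figure D2:**
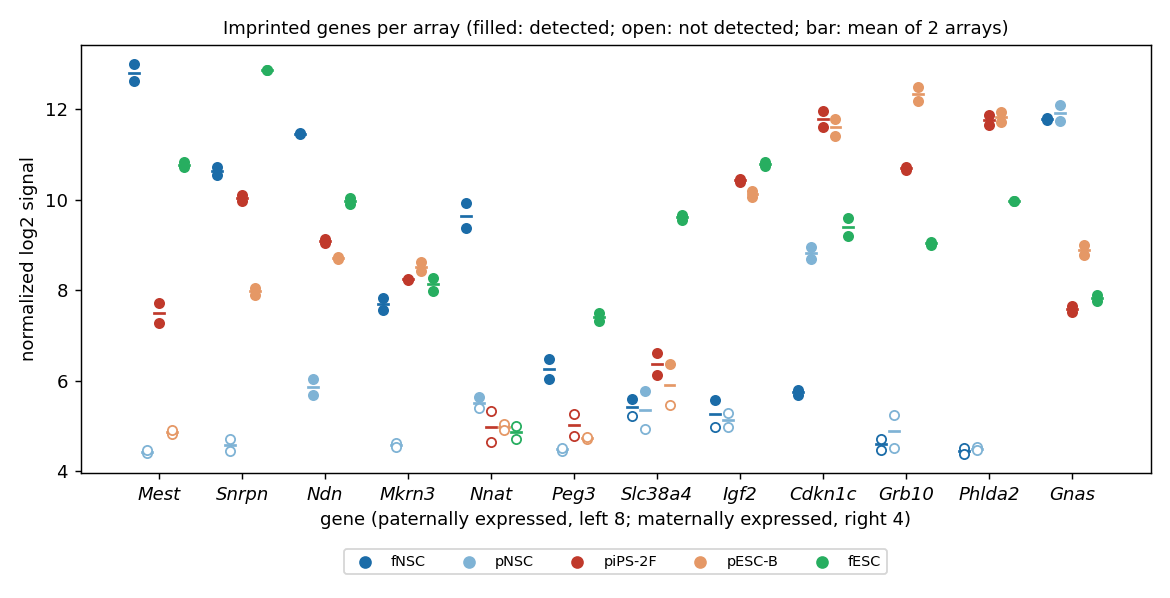
Log2 signals of imprinted genes in the 5 groups, with 1 point per array and a line at each group mean of 2 arrays. Mest lies at 12.81 in fNSC and 10.77 in fESC, at 4.43 in pNSC and 4.87 in pESC-B, and at 7.50 in piPS-2F.

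The difference between parthenogenetic and female lines was not the same in the pluripotent as in the neural lines. The interaction contrast of piPS-2F against fESC with pNSC against fNSC called 2640 genes, 1326 positive and 1314 negative, and that of pESC-B against fESC with pNSC against fNSC called 2791, 1470 positive and 1321 negative. With an offset of 50 they called 1592 and 1760. Of the 2640 and 2791 genes, 561 and 531 were called between pNSC and fNSC but not between the pluripotent lines, and 1380 and 1574 between the pluripotent lines only. A further 155 and 169 were called on both sides, and 544 and 517 on neither side. The pluripotent side sets the dimmest arrays against brighter ones, so for the genes called only there cell type and array brightness cannot be told apart. Ifitm3 gave 7.26 ± 0.22 and 7.04 ± 0.22 in the 2 contrasts and Ecrg4, undetected in the 3 pluripotent lines, gave 6.30 ± 0.26 and 5.78 ± 0.26. Chchd10 gave -6.66 ± 0.20 and -6.12 ± 0.20. Mest gave 5.10 ± 0.25 and 2.47 ± 0.25, Ndn 4.71 ± 0.20 and 4.32 ± 0.20, and Slc38a4 -3.18 ± 0.47 and -3.64 ± 0.47. Mest was undetected in pNSC and pESC-B, so its second value mostly follows the levels of fNSC and fESC (12.81 and 10.77) and does not show whether the gap between parthenogenetic and female lines changed. Slc38a4 was detected on 1 of 2 arrays in each neural line and in pESC-B. A positive value means that the parthenogenetic line lay lower against the female line in neural than in pluripotent cells, or higher against it in pluripotent than in neural cells. Epithelial genes were called in the first contrast, with 6 of 10 members negative (adjusted p = 0.035, and 0.41 with an estimated correlation). That call was lost without fNSC replicate 2 or piPS-2F replicate 1 (adjusted p = 0.051 and 0.052). In the second contrast 6 of 8 germline genes were negative (adjusted p = 0.0063, and 0.26 with an estimated correlation), and 7 of 8 primed epiblast genes were positive (adjusted p = 0.0063, and 0.54 with an estimated correlation). The paternally expressed genes went 6 up and 3 down of 15 in the first (adjusted p = 0.20) and 7 up and 3 down in the second (adjusted p = 0.72).

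Genes that set piPS-2F apart from both embryonic lines numbered 148 higher and 141 lower, 289 in all. An offset of 50 gave 123 and the authors' values gave 450. Independent lists of these sizes would share 47.7 and 55.5. The 2 comparisons share the piPS-2F arrays, and simulated unchanged groups gave 0.01 such genes on average and at most 1. As that simulation changed no gene in any group, it left few calls that could overlap. It does not measure what the shared arrays add among genes that differ. The differences correlated at 0.25 across genes, against 0.50 for simulated unchanged groups, with a covariance of 0.164 against 0.0174. Part of the excess may come from the shared arrays, since 2 arrays cannot be split. Slc4a3 and Cdc42ep2 led the higher genes, followed by A3galt2, Txnip, a thioredoxin-binding protein gene, Obox6 and the germ cell gene Nanos3 (2.65 ± 0.19 against pESC-B and 3.06 ± 0.19 against fESC). Trim59, Cops8, Atf4, Olig1, Rpusd4 and Tomm22 led the lower genes. Of the 141 lower genes, 69 (48.9%) were also lower and 12 higher in pNSC than in both embryonic lines, where 1566 of all 9220 genes were lower. Of the 148 higher genes, 32 (21.6%) were also higher and 26 lower, where 1716 were higher. These counts use the same embryonic arrays as the selection, and their size without any change was not computed.

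In all 6 pairwise comparisons, the numbers of list members called when adjusted over the list alone equalled those over all genes. Of 120 list tests 26 were called, and 6 held with an estimated correlation: pluripotency and neural stem cell genes in piPS-2F against pNSC and in fESC against fNSC, epithelial genes between fESC and fNSC, and paternally expressed genes between pNSC and fNSC. In 22 list tests, of which none was called, the median, the mean and the direction of the test differed in sign.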

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

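All tests of explanations in this part were chosen after the results were seen, while the interaction contrasts themselves were planned. What drew attention here was a difference between groups: the gap between a parthenogenetic and a female line was not the same in pluripotent as in neural stem cells. No group had enough arrays for a test of single outlying arrays.

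For piPS-2F against fESC, set against pNSC and fNSC, 2640 genes passed, among them 12 imprinted genes that were named. Mest gave 5.10, Ndn 4.71, Nnat 4.26, Mkrn3 3.24, Snrpn 3.23, Nap1l5 2.41, Atp10a 2.03, Phlda2 1.75 and Grb10 1.37. Slc38a4 gave -3.18, Ube3a -1.62 and Dlk1 -1.36. For several genes 1 side of the contrast lay at background, so that the gap differed because the gene was not expressed there: Nnat and Nap1l5 were undetected in piPS-2F, pESC-B and fESC, and Phlda2, Grb10 and Dlk1 in both neural lines. Mest, Snrpn and Mkrn3 were undetected in pNSC and Atp10a in fESC, so the size of their gap is not known there. The mean of the probes ended the calls of Snrpn (0.82) and Ube3a (-0.72), and the authors' values and the test against a 1.5-fold minimum ended that of Grb10.

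For pESC-B against fESC, set against the same neural lines, 2791 genes passed. Ndn gave 4.32, Nnat 4.25, Mkrn3 3.51, Grb10 3.02, Mest 2.47, Atp10a 2.45, Nap1l5 2.38, Ppp1r9a 2.21, Phlda2 1.81 and Slc22a18 1.67, which was undetected in fESC and both neural lines and gave 0.81 with an offset of 50. Mest was also undetected in pESC-B, so its 2.47 mostly follows the levels of fNSC and fESC and does not show whether the gap changed. Slc38a4 gave -3.64 and Ube3a -2.27. Of the 2640 and 2791 genes, 561 and 531 were called between pNSC and fNSC and not between the pluripotent lines, among them Ifitm3 (-6.79 between the neural lines) and Chchd10 (5.93), and that comparison does not cross the dimmer and brighter sets of arrays. For the 1380 and 1574 called between the pluripotent lines only, an array batch and the cell type cannot be told apart. The others were called on both sides (155 and 169) or on neither (544 and 517).

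Mest and Snrpn were higher in piPS-2F than in both pNSC and pESC-B, which are of the same parental origin. Snrpn reached 66.3% of its fNSC signal where neural stem cell genes reached a median of 2.87%, a ratio of 0.0434. This argues against RNA of fNSC-like cells as the source of Snrpn. Mest reached 2.32%, below that median, so the same measure does not argue against such RNA for Mest. Another measure, added after the neural shares were seen, counted genes bright in fNSC that stayed under 0.5 times the Mest share. It found 29 of 1007, among them Olig1 at 0.0902% and Fabp7 at 0.171%. These low genes go against fNSC-like RNA for Mest. Probes of one gene also disagreed most often between fNSC and piPS-2F (17.6%), and how far this lowered single genes was not tested. RNA of fESC cells stays open. Of 830 genes bright in fESC and pESC-B, 2 stayed under 0.5 times the 9.54% that Mest reached, Atf4 and Tomm22 at 3.11% and 3.48% of the fESC signal. These genes go against it, but they were fewer than the test had required to argue against it. That test replaced an earlier form whose only gene was Zscan4c (38.7%). Feeder RNA also stays open, as the feeder list had a median difference of 0.571 against 2.07 for Snrpn and only pESC-B is labelled as sorted, and a partial change of imprinting during reprogramming may contribute but was not tested, and neither was an array batch.

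Probes of the same gene often disagreed between piPS-2F or pESC-B and the other 3 lines. The share of genes whose probes differed by over 2 was 10.1% to 17.6% in pairs across these sets and 0.919% to 7.83% in pairs within them. Whether an array or labelling batch underlies this was not tested, and the labels name none. Probes near background are argued against, as the share in piPS-2F against fESC was 6.71 times that in fESC against fNSC among probes detected on all arrays. Sequence variants of the parthenogenetic line as the whole source are argued against by pNSC, which shares that origin and still gave 2.02 times the share of fESC against fNSC when compared with piPS-2F.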

How the results depend on the processing

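Median scaling and the crossed pairing were chosen after the data were seen, and all other alternatives were planned. The planned block for slides was not run because the column names give no slide.

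The named genes made 421 pairs of a gene and a comparison. Without a filter on dim probes, with an intensity trend, and with the replicate block, all 421 kept their direction and side of the threshold. The counts were 364 with an offset of 50, 409 without background correction, 412 with the authors' values, 399 with the mean of probes, 403 with median scaling and 396 with the test against a 1.5-fold minimum. Mobp in piPS-2F vs fESC reversed, to -0.57 without background correction and -0.96 with the authors' values. Its 3 probes ran from -0.69 to 1.19 with the main processing, and the brightest probe was chosen anew under each alternative. Whether another probe was used was not tested.

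With an offset of 50 the called genes were 391 in piPS-2F vs pESC-B, 1269 in piPS-2F vs fESC (469 higher and 800 lower), 593 in pNSC vs fNSC, 1503 in pESC-B vs fESC, and 1592 and 1760 in the interaction contrasts with piPS-2F and pESC-B. Genes that set piPS-2F apart from both embryonic lines numbered 123. A larger offset shrinks differences by construction. The gap in array similarity was 0.0507 in favour of pESC-B over fESC as the neighbour of piPS-2F. It became 0.0479 with this offset, 0.0492 without background correction, 0.0277 without a filter and 0.0795 for probes detected on all 10 arrays. The cause of these changes was not tested. This gap also runs along the dimmer and brighter sets of arrays. The authors' values gave 450 genes apart from both embryonic lines, and the cause was not tested.

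Keeping only probes detected on all 10 arrays left fewer genes to test. It gave 2624 genes in piPS-2F vs pNSC, 300 in piPS-2F vs pESC-B, 1114 in piPS-2F vs fESC, 403 in pNSC vs fNSC, 1300 in pESC-B vs fESC, 2309 in fESC vs fNSC, and 1237 and 1340 in the interaction contrasts. It gave 1675 concordant genes, 91 apart from both embryonic lines, and 9 called lists.

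The adjusted p alone, which drops the fold minimum, called 2766 genes in piPS-2F vs pESC-B, 5228 in piPS-2F vs fESC, 2962 in pNSC vs fNSC, 5546 in pESC-B vs fESC, 6955 in fESC vs fNSC, 4208 and 4485 in the interaction contrasts, 5415 concordant genes and 1164 apart from both embryonic lines. The stricter test against a 1.5-fold minimum called 580 in piPS-2F vs pESC-B and 1706 in the interaction contrast with piPS-2F. Of the list tests, 6 were called with an estimated correlation, which widens their error, and 85 by fry, which tests each list by itself and not against other genes.

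With median scaling the median of all genes was 0.22 in piPS-2F vs pNSC, 0.21 in piPS-2F vs fESC and 0.12 in fESC vs fNSC. The replicate block gave 4926, 870, 2184, 1044, 2487 and 4485 genes in the 6 pairwise comparisons in the order of piPS-2F vs pNSC, pESC-B and fESC, pNSC vs fNSC, pESC-B vs fESC and fESC vs fNSC. It left 25 called lists, without cell cycle genes in piPS-2F vs pESC-B (adjusted p = 0.052). Replicate numbers showed no shared pairing across groups, with correlations of -0.122 to 0.0875, and the crossed pairing called 1045 genes in pNSC vs fNSC.

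Leaving out each array in turn assumes that the remaining array of its group varies like the others. It gave 4918 to 4941 genes in piPS-2F vs pNSC, 865 to 976 in piPS-2F vs pESC-B, 2180 to 2262 in piPS-2F vs fESC, 1001 to 1082 in pNSC vs fNSC, 2483 to 2573 in pESC-B vs fESC and 4459 to 4528 in fESC vs fNSC. The interaction contrasts gave 2521 to 2669 and 2695 to 2833, the concordant genes 3227 to 3266, those apart from both embryonic lines 288 to 344, and the called lists 23 to 28. Signal over background limits dim genes, as between 38.7% and 46.1% of probes were detected per array.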

Other observations

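The shift of chromosome 1 was itself noticed in these data, and its tests were chosen before the values they measure were seen. Imprinted genes also differed between the 2 female lines, where both parental copies are present. In fESC against fNSC, 9 of 15 paternally expressed genes were higher and 5 lower (adjusted p = 0.26), and of 16 maternally expressed genes 5 were higher and 5 lower (0.93). Igf2 rose by 5.51 ± 0.19, and Phlda2 and Grb10 were at least 24.2-fold and 12.6-fold higher. Nap1l5 and Nnat, which is active in developing brain, were at least 18.3-fold and 13.3-fold lower, and Gnas fell by 3.95 ± 0.16. Of 7 genes of MHC class I presentation, 3 fell (adjusted p = 0.17), with B2m at -2.49 ± 0.21.

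Single members of lists that were not called also differed between the neural lines (feeder fibroblast genes, adjusted p = 0.54, and extraembryonic endoderm genes, 0.41). Thy1, a glycoprotein gene of neurons and fibroblasts, rose by 3.17 ± 0.24 in pNSC, and the lipoprotein gene Apoe rose by 3.09 ± 0.13. The crosslinking enzyme gene Loxl1 was at least 7.14-fold higher in pNSC, and the collagen gene Col6a1 at least 7.35-fold lower. Against fESC, piPS-2F and pESC-B shared 587 higher and 841 lower genes, where independent lists would share 151 and 143, but the 2 comparisons share the fESC arrays. Their differences correlated at 0.79 across genes, which are not independent replicates, against 0.50 for simulated unchanged groups. Both comparisons also set dimmer against brighter arrays. Of their called genes with several kept probes, 52.6% and 45.6% had another probe that differed by under 0.5. How much of the overlap follows the sets of arrays was not tested.

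Genes of chromosome 1 lay higher in piPS-2F. Of its 452 tested genes, 75.7% lay above the median of the other autosomes in piPS-2F against pESC-B. The median shift was 0.369 where the other 18 autosomes gave -0.0839 to 0.0827, so a few strongly changed genes are argued against. Both measures come from the same differences, so the 75.7% is not support separate from the shift that was noticed. The shift was 0.331 with median scaling, which argues against quantile normalization. In piPS-2F against fESC it was 0.363, where the other autosomes gave -0.124 to 0.164. An array batch was not tested. Split into 4 runs of 113 genes, the chromosome gave 0.343 to 0.401, which argues against a local gene cluster and is what an extra chromosome 1 in part or all of the piPS-2F cells would need. Such a gain may be a candidate explanation and remains a hypothesis, since no DNA was measured. Against pNSC the shift was 0.162 (above 96.3% of random gene lists). This lay inside the range of -0.312 to 0.279 of the other autosomes, of which chromosomes 5, 7 and 8 lay higher. The comparison with pNSC alone cannot decide the question, as it also sets pluripotent against neural cells and dimmer against brighter arrays. Between fESC and fNSC, which also differ in cell type, chromosome 1 gave -0.161, the opposite sign. Chromosomes 5, 7 and 8 gave 0.0818, 0.277 and 0.146 there, and 0.169, 0.279 and 0.196 in piPS-2F against pNSC. Between pNSC and fNSC, chromosome 1 gave -0.0172, inside the range of the other autosomes (-0.129 to 0.0547). The cells of origin thus showed no such shift against fNSC.

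Genes of the X chromosome (328 tested) were shifted by 0.171 in piPS-2F against pNSC, 0.314 in piPS-2F against pESC-B, -0.196 in piPS-2F against fESC, -0.476 in pESC-B against fESC, 0.361 in fESC against fNSC and -0.0372 in pNSC against fNSC. The shifts of 0.171 and -0.0372 lay inside the ranges of the autosomes other than chromosome 1 (-0.312 to 0.279 and -0.129 to 0.0547). The remaining shifts lay outside those ranges in their comparisons.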
